A study of Mus musculus with 6 samples.

How the data were processed

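RNA was measured in 6 libraries of sorted 4T1 tumour endothelial cells, 3 nanoparticle-positive (NP+) and 3 nanoparticle-negative (NP-). The groups and the tumour of origin (MET-106, MET-107 and MET-108) come from the sample labels. RNA was extracted with Trizol and an RNeasy Plus Mini kit, made into libraries with SMART-Seq v4 and sequenced as paired 150 bp reads, per the labels' protocols. SMART-Seq v4 amplifies full-length cDNA and does not mark strand or molecules.

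The deposited files hold 1 whole-number count per gene and library. Per the submitters' processing notes, Trimmomatic 0.036, STAR 2.5.2b, featureCounts of Subread 1.5.2 and DESeq2 were used, with the mouse build GRCm38 (mm10). The annotation release and the strand and multi-mapping settings behind these deposited counts are not given in the sources used here. Counts of paralogs, overlapping genes and antisense genes are therefore uncertain. The authors' deposited table also gives a signal per library, which is the count divided by a size factor. It further gives the authors' log2 fold changes of NP- over NP+, and p-values and adjusted p-values deposited by the authors. Of its 156426 normalized values, 100% gave whole reads within 0.01 reads, and 100% equalled the deposited counts. The authors' deposited table holds the 26071 genes with a total count above 60, and 25298 of them have an adjusted p. The sign of 99.9% of its log2 fold changes matched NP- over NP+ means, so signs were turned here to NP+ over NP-.

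The count files list 49315 gene IDs, of which 48970 matched a symbol in the reference table and 49014 had a symbol once names in the deposited table were added. Coordinates come from the count files. Of the IDs, 49056 are in GENCODE mouse release 21, and 44858 have the same start and end there. Total gene counts ran from 20856410 to 58089600 per library. Reads carry no molecular identifiers, so limits from counts cover counting error only.

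The main test was edgeR's quasi-likelihood test without a block, with TMM scaling and filterByExpr by group (minimum count 10), which left 23989 genes. P values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are scaled by tested counts and TMM factors. The exceptions, per total gene counts, are the summed levels and folds of olfactory receptor, vomeronasal receptor, keratin-associated and beta-defensin genes. Shares of counts were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1. These tests treat the 6 libraries as exchangeable and ignore the shared tumours, and no paired test of the shares was run.

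Each NP+ library shares its tumour with 1 NP- library, per the labels. The correlation of same-tumour deviations from the group means was 0.28, 0.21 and 0.02. The fit with the tumour as a replicate block is an alternative, and the p values of the unblocked fit rest on the spread between 3 tumours.

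Lists of genes were fixed before the data were examined, as were the main test, the rule for named genes and the planned settings. The 32 lists cover endothelial subtypes (pan-endothelial, tip cell, venous, arterial, capillary and lymphatic), junctions, basement membrane and glycocalyx. They also cover entry routes (caveolae, clathrin, macropinocytosis, scavenger receptors, exocytosis and lysosome) and states (inflammatory activation, interferon, antigen presentation, proliferation, hypoxia, oxidative stress, immediate-early genes and mitochondrially encoded genes). The remaining lists are markers of macrophages, neutrophils, platelets, lymphocytes, epithelial cells, fibroblasts, pericytes, adipocytes and erythroid cells. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and members were adjusted over the list alone. Because fewer than 5 genes passed per direction, the rule named the 8 genes per direction with the smallest p, a mean of at least 5 CPM and the same direction in 3 of 3 tumours. It also named up to 4 members per list with the smallest p, and Pecam1 and Ptprc. The values of some genes that the rule names are not reported here.

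Alternatives were the tumour block, DESeq2, limma-voom, RLE, upper-quartile and total-count scaling, no low-count filter, at least 5 CPM in 3 libraries, and each library or tumour left out. Thresholds of 0.1 or a fold of at least 2 were tried too. Settings added after seeing the data were robust shrinkage, the block with the 5 CPM filter, limma-voom with the block, the reads recovered from the deposited signal values, and 5 further lists. The tests were tried on simulated data with known changes, drawn for 23989 genes from the observed means, library sizes and dispersion (median 0.362).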

Results

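Gene expression was measured in endothelial cells of 4T1 tumours, which grow from a transplantable mouse mammary carcinoma line. The tumours grew for 2 weeks in the mammary fat pad of female Balb/c mice. Each mouse received 1E12 gold nanoparticles, 50 nm across and coated with 5 kDa polyethylene glycol and the dye Cy5, by tail vein 1 hour before harvest. Cells depleted of CD45 (a leukocyte marker) and enriched for CD31 (an endothelial marker) were sorted by flow cytometry into nanoparticle-positive (NP+) and nanoparticle-negative (NP-) fractions. The 6 libraries are 1 NP+ and 1 NP- library from each of 3 tumours, named MET-106, MET-107 and MET-108. The comparison asks which transcripts separate tumour endothelial cells that carried nanoparticles from those that did not. Unless stated otherwise, levels are library-size-scaled counts (CPM) as mean ± SD over the 3 libraries of a group (n = 3).

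The NP+ libraries of tumours MET-106, MET-107 and MET-108 held 41830256, 58089600 and 44901340 gene counts, and the NP- libraries 44694267, 20856410 and 27396773. The mean was 48273732 ± 8638364 in NP+ and 30982483 ± 12316812 in NP- (exact two-sided permutation p = 0.2, where 0.1 is the smallest p that 3 against 3 libraries allow). The permutation tests in this paragraph ignore the pairing by tumour. Protein-coding genes took 97.7 ± 0.255% of the counts in NP+ and 96.4 ± 0.456% in NP- (exact permutation p = 0.1). The 10 highest genes took 5.72 ± 0.172% and 6.85 ± 0.178% (exact permutation p = 0.1). Mitochondrial genes took 1.19 ± 0.257% and 2.13 ± 1.55% (exact permutation p = 0.5), and the NP- library of tumour MET-106 stood at 3.9%. The number of genes with a count was 34520 ± 2991 in NP+ and 35911 ± 3354 in NP- (exact permutation p = 0.7). Pairwise correlations of log2 CPM ran from 0.959 to 0.970 among NP+ libraries and from 0.832 to 0.876 among NP- libraries. The NP- library of tumour MET-106 correlated at 0.951, 0.945 and 0.950 with the NP+ libraries of tumours MET-106, MET-107 and MET-108, and at 0.876 and 0.838 with the NP- libraries of tumours MET-107 and MET-108.

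Cd276, Prss23 and Fgfr1 were higher in NP+ cells, and Fhl1, Cd24a, Abi3bp and Ntrk2 were lower. Cd276, which encodes the immune checkpoint family protein B7-H3, stood at 389 ± 34.9 CPM in NP+ and 86.2 ± 20 CPM in NP-, 4.51 times as high. Prss23, a serine protease gene, stood at 1464 ± 48.2 against 512 ± 12.1 CPM. Fgfr1, a fibroblast growth factor receptor gene, stood at 116 ± 8.34 against 36.4 ± 4.18 CPM. On the lower side, Fhl1, a LIM domain protein gene, stood at 13.6 ± 0.269 CPM in NP+ and 54.9 ± 3.18 CPM in NP-. Cd24a, a surface glycoprotein gene, stood at 7.75 ± 1.21 against 38.5 ± 5.32 CPM. Abi3bp, an extracellular matrix protein gene, stood at 4.01 ± 1.15 against 31.5 ± 7.94 CPM, and Ntrk2, which encodes the neurotrophin receptor TrkB, at 1.95 ± 0.699 against 23.1 ± 7.16 CPM.

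These 3 higher and 4 lower genes were the ones with an adjusted p under 0.05 among 23989 genes tested (edgeR's quasi-likelihood test), each with the same direction in 3 of 3 tumours. All 7 had an adjusted p of 0.0379. The log2 fold changes (NP+ over NP-, with SE) were 2.17 (0.21) for Cd276, 1.52 (0.16) for Prss23 and 1.67 (0.18) for Fgfr1. They were -2.01 (0.19) for Fhl1, -2.31 (0.25) for Cd24a, -2.97 (0.33) for Abi3bp and -3.57 (0.40) for Ntrk2. With the tumour as a block 2 genes were higher and 13 lower. The blocked adjusted p was 0.0317 for Cd276 and Ntrk2, 0.0322 for Abi3bp, and 0.0588 for Prss23, Fgfr1, Fhl1 and Cd24a. At an unadjusted p under 0.05, 1922 genes were higher and 3684 lower. The split of 3 higher and 4 lower calls became 3 and 18 with upper-quartile scaling and 2 and 9 with total counts. The median log2 fold change of all tested genes was -0.29 with TMM, -0.53 with upper-quartile and -0.59 with total-count scaling. Without the NP+ library of tumour MET-106, MET-107 or MET-108, or the NP- library of tumour MET-107, 0 genes passed in either direction. Those 4 fits held 1139, 1701, 1113 and 1555 genes higher and 2289, 3739, 2334 and 2604 lower at an unadjusted p under 0.05. In fits without the NP- library of tumour MET-106 the counts were 968 higher and 1352 lower, and without that of tumour MET-108 they were 113 and 177.

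**Figure D1:**
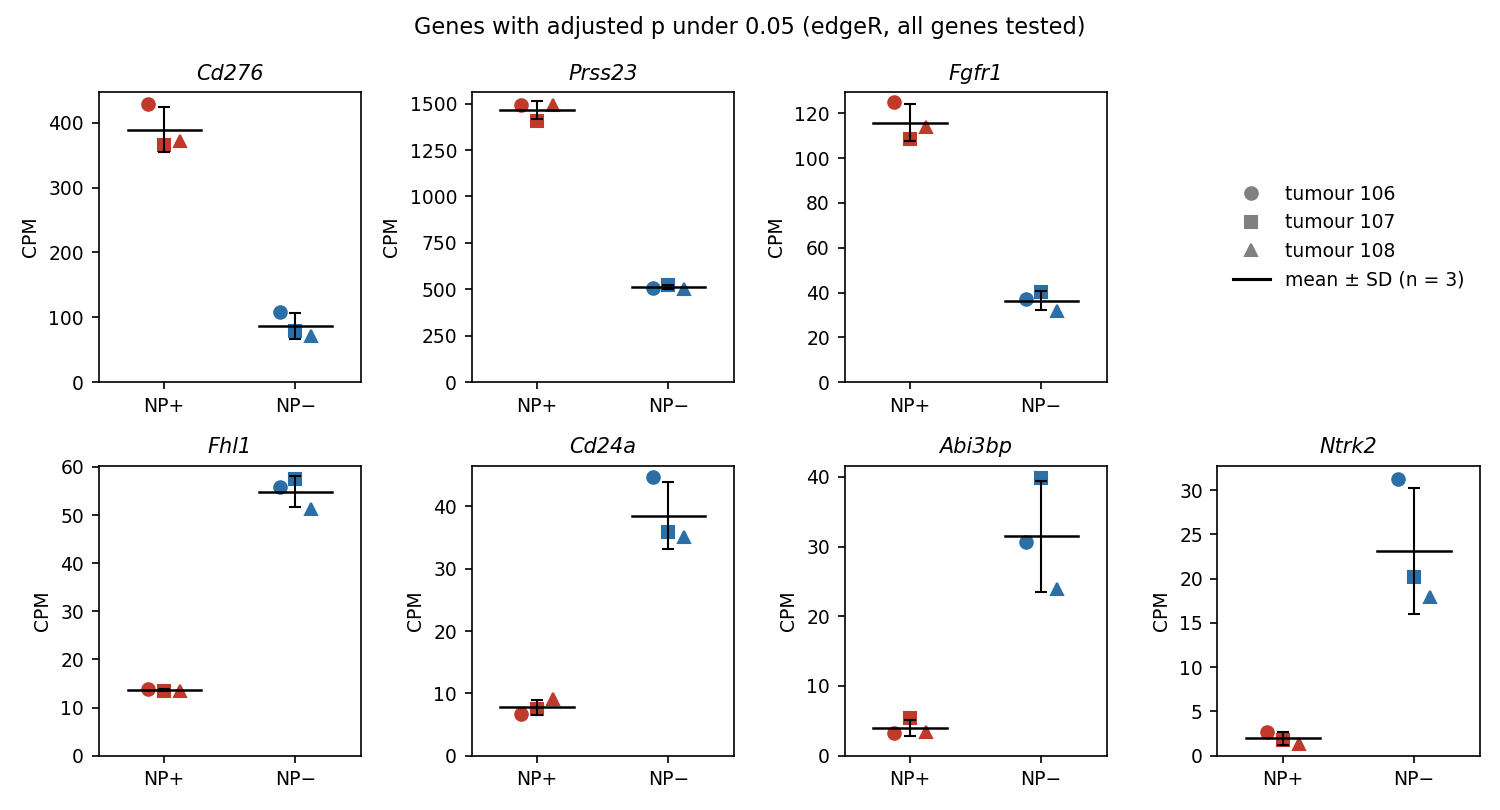
CPM (vertical axis, from 0) of the 7 genes that passed over all genes, in NP+ (red) and NP- (blue) libraries, with 1 symbol shape per tumour and black bars for mean ± SD (n = 3). The NP+ points of Cd276, Prss23 and Fgfr1 lie above every NP- point, and those of Fhl1, Cd24a, Abi3bp and Ntrk2 lie below.

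On GRCm38, Cd276 (ENSMUSG00000035914) lies on chromosome 9 from 58524298 to 58555437, minus strand. Prss23 (ENSMUSG00000039405) lies on chromosome 7 from 89507783 to 89527187, minus strand, and Fgfr1 (ENSMUSG00000031565) on chromosome 8 from 25513654 to 25575718, plus strand. Fhl1 (ENSMUSG00000023092) lies on chromosome X from 56731787 to 56793346 and Cd24a (ENSMUSG00000047139) on chromosome 10 from 43578284 to 43584265, both plus strand. Abi3bp (ENSMUSG00000035258) lies on chromosome 16 from 56477846 to 56690128 and Ntrk2 (ENSMUSG00000055254) on chromosome 13 from 58806596 to 59133970, both plus strand. All 7 are annotated as protein-coding, and the counts cover their exons as a whole.

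The next genes by p did not pass over all genes. Ptprm, a receptor tyrosine phosphatase gene, stood at 237 ± 24.6 CPM in NP+ and 89.6 ± 6.62 CPM in NP- (adjusted p = 0.0527), and its relative Ptprg at 246 ± 11.8 against 105 ± 12.1 CPM (0.0600). Sema7a, a semaphorin gene, stood at 46.6 ± 6.21 against 14.5 ± 2.17 CPM (0.0600). Dock4, a Rac exchange factor gene, stood at 118 ± 14.9 against 45.8 ± 4.54 CPM (0.0600), and Ephb4, the venous ephrin receptor gene, at 179 ± 19.5 against 74.9 ± 5.87 CPM (0.0600). Cp, the ceruloplasmin gene, stood at 28.3 ± 3.97 CPM in NP+ and 107.4 ± 26.2 CPM in NP- (0.0527), and Ephx1, an epoxide hydrolase gene, at 5.99 ± 0.819 against 25.0 ± 3.46 CPM (0.0600). Olfr558, an olfactory receptor gene, stood at 0.525 ± 0.160 against 10.1 ± 3.46 CPM (0.0549). Prlr, the prolactin receptor gene, stood at 1.08 ± 0.162 against 11.7 ± 3.56 CPM (0.0569). The NP- level of Prlr was 2.74 times, and that of Olfr558 11.9 times, the level that the counts in olfactory receptor genes give for a gene of its length. That level is a mean density times gene length, without a spread between genes. Such ratios, here and below, therefore do not place a single gene above or below background. Of the sorting markers, Pecam1, the CD31 gene, stood at 3291 ± 500 CPM in NP+ and 2353 ± 449 CPM in NP- (adjusted p = 0.211). Ptprc, the CD45 gene, stood at 4.48 ± 0.997 against 13.9 ± 10.4 CPM (adjusted p = 0.150), with 25.7 CPM in the NP- library of tumour MET-107 and an NP- mean of 8.02 CPM without it. The NP- mean of Ptprc over 3 libraries was 2.73 times the level that the counts in olfactory receptor genes give for its length.

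Across 32 gene lists fixed before the data were examined, 146 of 679 memberships passed when adjusted over the list alone, 55 higher and 91 lower in NP+. Over all genes tested, the lowest adjusted p among the members was 0.0600. "Rose" and "fell" below refer to an adjusted p under 0.05 adjusted over the list alone. With camera at a preset correlation of 0.01, 14 lists were called up and 7 down. Other splits of the 6 libraries into 3 and 3 also gave 12 to 16 called lists at this preset. The estimated correlation ran from -0.0299 for platelet to 0.938 for mitochondrially encoded genes, with 0.26 for tip cell and 0.79 for fibroblast genes. With an estimated correlation 0 of the 32 were called, and the adjusted p ran from 0.222 to 0.978. The rotation test fry, which asks whether a list moves one way on balance, called 6 lists and, with the tumour as a block, 1.

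**Figure D2:**
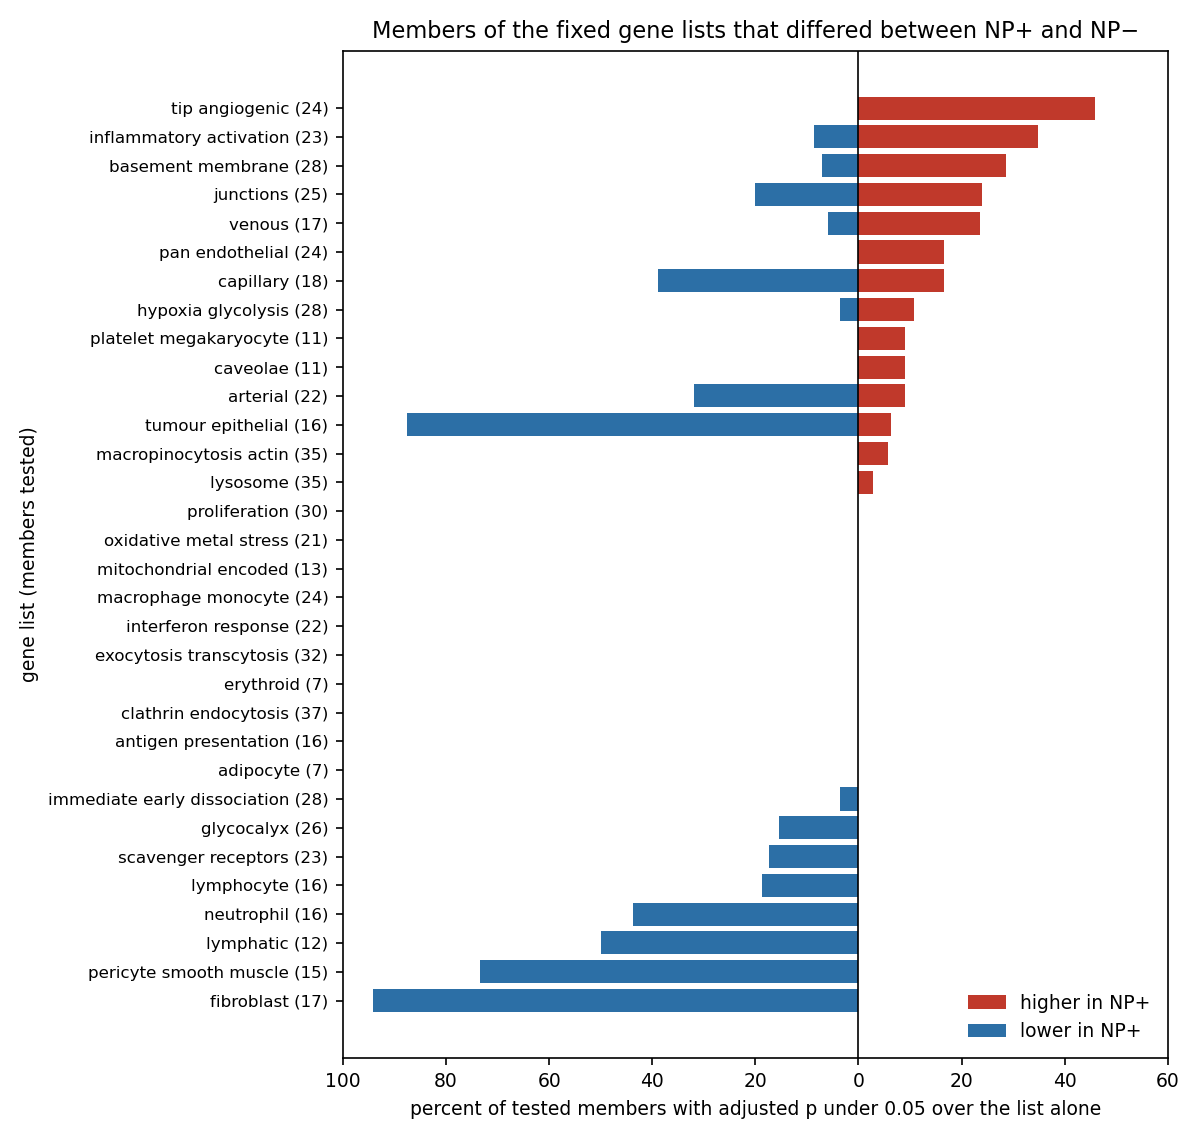
Percent of tested members of each of the 32 fixed gene lists that were higher (red, right) or lower (blue, left) in NP+ with an adjusted p under 0.05 over the list alone. The number of members tested is in brackets, and the bars start at 0. The tip cell and angiogenic list has 11 of 24 members higher, and the fibroblast list 16 of 17 members lower.

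Tip cell and angiogenic genes rose in NP+ cells, with 11 of 24 members higher and 0 lower. Apln, an angiogenic peptide gene of tip cells, stood at 592 ± 102 CPM in NP+ and 92.5 ± 53.0 CPM in NP-, 6.40 times as high (adjusted p = 0.000833, adjusted over the list alone). Esm1, another tip cell marker, stood at 169 ± 21.4 against 58.4 ± 12.2 CPM (0.000833). Trp53i11 stood at 2278 ± 254 against 642 ± 234 CPM (0.000946), and Col4a2, a basement membrane collagen gene, at 5506 ± 378 against 2401 ± 573 CPM (0.00231). The list's median log2 fold change was 0.74, against -0.29 for all tested genes (camera adjusted p = 2.34e-14, adjusted p = 0.222 with an estimated correlation). Pan-endothelial genes had a median of 0.47, and all genes had a median of -0.02 in the fit that kept those with at least 5 CPM in 3 libraries. The fry adjusted p of the tip cell list was 0.0489, and 0.161 with the tumour as a block. The count was 17 by limma-voom and 4 with upper-quartile or total-count scaling. It was 6 without the NP- library of tumour MET-106, 23 without that of tumour MET-108 and 4 without the NP+ library of tumour MET-107.

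Pan-endothelial genes rose for 4 of 24 members and fell for 0. They were Sox17 (66.1 ± 13 against 26.5 ± 7.31 CPM), an endothelial transcription factor gene, Clec14a (398 ± 42.1 against 257 ± 15.2 CPM), Flt1 (1243 ± 181 against 529 ± 232 CPM), a VEGF receptor gene, and Eng (1558 ± 140 against 946 ± 168 CPM), a BMP co-receptor gene. The median log2 fold change was 0.47 (camera adjusted p = 3.64e-09, adjusted p = 0.222 with an estimated correlation). In the blocked fit 1 member rose, and with upper-quartile or total-count scaling 0 did. By DESeq2 15 members were higher and by limma-voom 18, and 13 at an unadjusted p under 0.05. The count was 1 without the NP- library of tumour MET-106 or the NP+ library of tumour MET-106, 17 without the NP- library of tumour MET-108, 7 without the NP+ library of tumour MET-107 and 0 without that of tumour MET-108. The members' summed level in tumours MET-106, MET-107 and MET-108 was 25558, 22029 and 24522 CPM in NP+ and 14216, 17087 and 18394 CPM in NP-.

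Venous genes rose for 4 of 17 members and fell for 1. Ephb4 rose (adjusted p = 0.000825, adjusted over the list alone), and so did Selp, the gene of the leukocyte adhesion protein P-selectin, at 1635 ± 663 CPM in NP+ and 430 ± 189 CPM in NP- (0.00537). Vcam1, another leukocyte adhesion gene, stood at 325 ± 70.0 against 171 ± 25.1 CPM (0.00904). The list had a median log2 fold change of 0.34 (camera adjusted p = 0.00136, adjusted p = 0.323 with an estimated correlation). The camera call was lost when only genes with at least 5 CPM in 3 libraries were kept (adjusted p = 0.194), a filter under which the median of all genes was -0.02. With total-count scaling 2 members rose. In the absence of the NP- library of tumour MET-106, 8 rose, and without that of tumour MET-107 or MET-108, 2 fell.

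Genes of inflammatory activation rose for 8 of 23 members and fell for 2. Besides Selp and Vcam1, Icam1, a leukocyte adhesion gene, stood at 939 ± 254 CPM in NP+ and 394 ± 30.1 CPM in NP- (adjusted p = 0.00751, adjusted over the list alone). Relb, an NF-kappaB subunit gene, stood at 114 ± 23.5 against 29.6 ± 14.9 CPM (0.00751). The median log2 fold change was 0.45 and the mean -0.02, while the camera test pointed up (adjusted p = 0.00108, adjusted p = 0.339 with an estimated correlation). With the tumour as a block 8 members rose and 4 fell, and with upper-quartile or total-count scaling 4 rose and 3 fell. In a fit that left out the NP- library of tumour MET-107, 4 rose and 3 fell, and the camera call was lost (adjusted p = 0.0913). Without the NP+ library of tumour MET-107, 5 rose and 1 fell, and without the NP- library of tumour MET-106, 9 rose and 1 fell.

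Arterial and capillary genes moved both ways. Of 22 arterial genes, 2 rose and 7 fell. Gja4, an arterial connexin gene, stood at 109 ± 14.5 CPM in NP+ and 232 ± 54.0 CPM in NP- (adjusted p = 0.00448, adjusted over the list alone), Mgp at 16.7 ± 5.13 against 57.2 ± 7.32 CPM (0.00246) and Alpl at 1.18 ± 0.0706 against 14.3 ± 11.4 CPM (0.00246). The NP- mean of Alpl was 7.71 CPM without the library of tumour MET-107. Sox17 was among the 2 that rose. The NP- level of 1 of the 7 that fell, Hey2 (named after its values were seen), lay within 2 times what the counts in olfactory receptor genes give. Of 18 capillary genes, 3 rose and 7 fell. Lpl, the lipoprotein lipase gene, stood at 25.9 ± 8.17 against 131 ± 44.5 CPM (0.000788), Aqp7, a glycerol channel gene, at 14.1 ± 1.87 against 80 ± 37.2 CPM (0.000788), and Cd36, a fatty acid and scavenger receptor gene, at 1228 ± 69.3 against 2117 ± 82.2 CPM (0.00477). Plvap, which encodes the protein of fenestral and caveolar diaphragms, rose, with 1691 ± 272 CPM in NP+ and 295 ± 251 CPM in NP- (0.00477). Its NP- levels in tumours MET-106, MET-107 and MET-108 were 585, 167 and 134 CPM, and the mean NP+ level was 5.72 times the mean NP- level, or 11.2 times without the NP- library of tumour MET-106. The camera test called neither list (adjusted p = 0.143 for arterial and 0.388 for capillary), but the arterial list was called down with upper-quartile (0.0208) and total-count scaling (0.0101). Both lists were called down when only genes with at least 5 CPM in 3 libraries were kept (6.28e-05 and 0.000459). With upper-quartile or total-count scaling 1 arterial and 1 capillary gene rose. In fits without the NP+ library of tumour MET-108, 1 arterial gene rose and 2 fell, and 1 capillary gene rose and 3 fell. Without that of tumour MET-106, 1 capillary gene rose and 4 fell. In the absence of the NP- library of tumour MET-106, 1 arterial gene rose, and without that of tumour MET-108, 4 arterial and 5 capillary genes did.

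**Figure D3:**
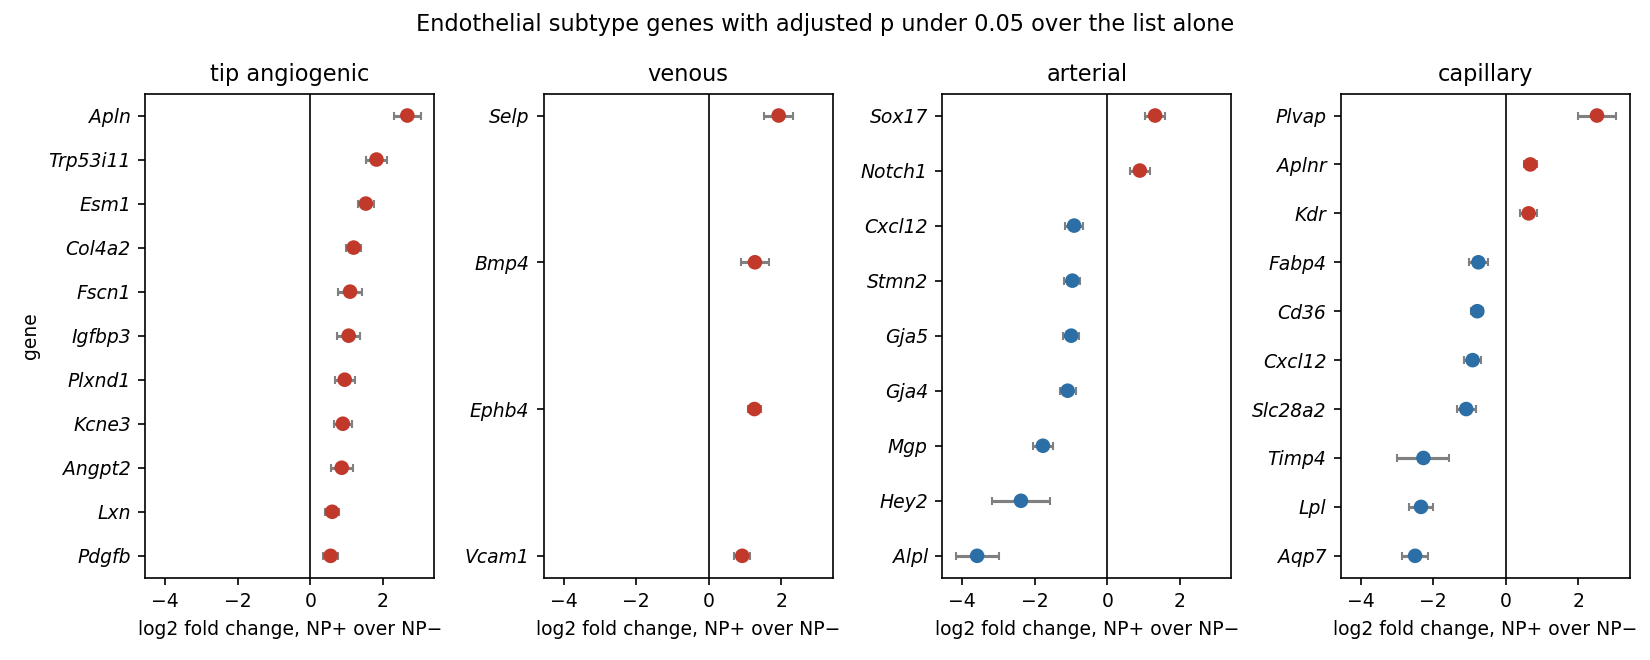
Log2 fold change of NP+ over NP- (horizontal axis, TMM scaling, bars are SE, n = 3 per group) for the reported members of the tip cell and angiogenic, venous, arterial and capillary lists with an adjusted p under 0.05 over the list alone. Red points are higher and blue points lower in NP+. All 11 tip cell genes lie right of 0, and 7 arterial and 7 capillary genes lie left of it.

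Lymphatic endothelial genes fell for 6 of 12 members. Prox1, the lymphatic master transcription factor gene, stood at 14.4 ± 2.18 CPM in NP+ and 41.3 ± 29.5 CPM in NP-, Reln at 11.1 ± 3.44 against 50.9 ± 44.4 CPM and Fgl2 at 51.7 ± 4.65 against 230.1 ± 198 CPM (adjusted p = 0.0345 for each, adjusted over the list alone). Leaving out the NP- library of tumour MET-107, the NP- means were 25.2, 27.6 and 120.1 CPM. The camera adjusted p was 0.0134, and the adjusted p was 0.549 with an estimated correlation. The summed level of the list was 724, 2868 and 1586 CPM in the NP- libraries of tumours MET-106, MET-107 and MET-108 and 1079, 1200 and 978 CPM in the NP+ libraries. In a fit that left out the NP- library of tumour MET-107, or the NP+ library of tumour MET-106 or MET-108, 0 members fell. At an unadjusted p under 0.05 6 members fell with all libraries, and 6 with DESeq2 and 0 with limma-voom when adjusted over the list alone. The camera call was lost without the NP- library of tumour MET-107 (adjusted p = 0.221) and the NP+ library of tumour MET-108 (0.0753).

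Junction genes rose for 6 of 25 members and fell for 5. The connexin genes Gja4 and Gja5 (78.9 ± 1.94 against 157 ± 40.6 CPM) and the tight junction gene Ocln (0.852 ± 0.205 against 5.4 ± 2.29 CPM) fell (adjusted p = 0.0116 for each, adjusted over the list alone). Ctnnb1, the beta-catenin gene, rose, with 928 ± 148 CPM in NP+ and 367 ± 173 CPM in NP- (0.0178). The list had a median log2 fold change of 0.36 and a mean of -0.15, and camera did not call the list (adjusted p = 0.0932). It was called up with limma-voom (0.0378) and with no low-count filter (0.00126), and without the NP+ library of tumour MET-106 (0.0148), MET-107 (0.0119) or MET-108 (0.0158) or the NP- library of tumour MET-108 (0.00410). With upper-quartile scaling 1 member rose and with total counts 0. Without the NP+ library of tumour MET-106 or MET-108, 0 rose and 0 fell by edgeR, where 9 rose and 5 fell at an unadjusted p under 0.05 with all libraries, and 12 and 5 by DESeq2 and by limma-voom. In fits without the NP- library of tumour MET-106, 3 rose, and without that of tumour MET-108, 13 did.

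Basement membrane genes rose for 8 of 28 members and fell for 2. Besides Col4a2, Lamc1, a laminin chain gene, stood at 266 ± 64.5 CPM in NP+ and 145 ± 17.2 CPM in NP-. Itgb1, the beta-1 integrin gene, stood at 2200.2 ± 213 against 799.9 ± 418 CPM, and Itga2 at 61.4 ± 3.17 against 32.6 ± 7.98 CPM (adjusted p = 0.0221 for each of the 3, adjusted over the list alone). The median log2 fold change was 0.57 (camera adjusted p = 6.09e-07, adjusted p = 0.222 with an estimated correlation). In the blocked fit 7 rose and 1 fell. The count of rising members was 14 with RLE, 2 with upper-quartile and 1 with total-count scaling. It was 5 without the NP- library of tumour MET-107, 15 without that of tumour MET-108 and 0 without the NP+ library of tumour MET-106, against 15 at an unadjusted p under 0.05 and 16 by DESeq2 or limma-voom with all libraries. The number that fell was 1 without the NP- library of tumour MET-107 or the NP+ library of tumour MET-108, and 0 without the NP+ library of tumour MET-106.

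Hypoxia and glycolysis genes rose for 3 of 28 members and fell for 1. Pdk1, a pyruvate dehydrogenase kinase gene, stood at 65.8 ± 9.21 CPM in NP+ and 25.9 ± 7.44 CPM in NP-, and the glycolytic genes Pfkl and Pgk1 at 343 ± 40.2 against 178 ± 36.1 CPM and 339.6 ± 17.2 against 198 ± 53.2 CPM (adjusted p = 0.00759, 0.0106 and 0.0412, adjusted over the list alone). Hk2, a hexokinase gene, fell, with 1.35 ± 0.460 CPM in NP+ and 10.8 ± 5.43 CPM in NP- (0.00759). The list had a median log2 fold change of 0.49 (camera adjusted p = 7.49e-07, adjusted p = 0.339 with an estimated correlation). The rising count was 12 by DESeq2, 14 by limma-voom, 10 with RLE and 1 with upper-quartile or total-count scaling, and 21 without the NP- library of tumour MET-108.

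Of the lists of entry routes, macropinocytosis and actin genes rose for 2 of 35 members and fell for 0. Snx9, a membrane remodelling sorting nexin gene, stood at 47.1 ± 0.869 CPM in NP+ and 14.0 ± 5.64 CPM in NP- (adjusted p = 0.00968, adjusted over the list alone), and Actr3, an Arp2/3 subunit gene, at 945 ± 75.4 against 560.4 ± 60.1 CPM (0.0307). The median log2 fold change was 0.38 (camera adjusted p = 2.11e-06, adjusted p = 0.222 with an estimated correlation). The fry adjusted p was 0.00657, and 0.00186 with the tumour as a block, under which 1 member rose. With upper-quartile or total-count scaling 1 member rose. Leaving out 1 library gave 4, 0 and 15 rising members for the NP- libraries of tumours MET-106, MET-107 and MET-108, and 1, 1 and 0 for the NP+ libraries, with 1 falling member without the NP- library of tumour MET-106 or MET-108. With all libraries, 12 were higher and 1 lower at an unadjusted p under 0.05, and 6 higher by DESeq2 or limma-voom.

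Plvap was the 1 of 11 caveolae and diaphragm genes that rose, and Cav1, the caveolin gene, stood at 3369 ± 257 CPM in NP+ and 2497 ± 119 CPM in NP- (adjusted p = 0.0839, adjusted over the list alone). The caveolae list was called up by camera (adjusted p = 0.00120, adjusted p = 0.324 with an estimated correlation), but not among genes with at least 5 CPM in 3 libraries (0.0751). The rising count was 4 by DESeq2 or limma-voom, and 4, 2 and 4 without the NP- library of tumour MET-106, MET-107 or MET-108, and 2 members fell without the last of these.

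In the clathrin list 0 of 37 members passed in either direction by edgeR, against 10 higher and 5 lower at an unadjusted p under 0.05, 4 and 5 by DESeq2 and 3 and 0 by limma-voom. Ap2a2, an AP-2 adaptor gene, stood at 151 ± 17.9 against 64.5 ± 23.8 CPM and Dnm2, a dynamin gene, at 304 ± 31.6 against 196 ± 21.7 CPM (adjusted p = 0.0596 for each, adjusted over the list alone). The clathrin median log2 fold change was 0.26 and the mean -0.12, and the median turned negative with upper-quartile (-0.02) and total-count scaling (-0.06). Camera called the list up (adjusted p = 0.00271, adjusted p = 0.323 with an estimated correlation), but not among genes with at least 5 CPM in 3 libraries (0.342). In the absence of the NP- library of tumour MET-106, 5 rose and 3 fell, without that of tumour MET-107, 1 rose, and without that of tumour MET-108, 9 rose and 2 fell.

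In the exocytosis and transcytosis list 0 of 32 members passed by edgeR, against 6 higher at an unadjusted p under 0.05, 4 by DESeq2 and 5 by limma-voom. Rab8b, a vesicle transport GTPase gene, stood at 252 ± 20.3 CPM in NP+ and 150.4 ± 31.0 CPM in NP- (adjusted p = 0.0797, adjusted over the list alone). Camera called the list up (adjusted p = 8.73e-05, adjusted p = 0.323 with an estimated correlation), but not among genes with at least 5 CPM in 3 libraries (0.492). With the tumour as a block 1 member rose, without the NP- library of tumour MET-106, 6, and without that of tumour MET-108, 3.

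Of 35 lysosome genes 1 rose when adjusted over the list alone. In the blocked fit or with upper-quartile or total-count scaling, 0 rose by edgeR, against 11 at an unadjusted p under 0.05, 2 by DESeq2 and 3 by limma-voom. The list was called up by camera (adjusted p = 1.46e-05, adjusted p = 0.323 with an estimated correlation) and by fry (0.0489), but not by camera among genes with at least 5 CPM in 3 libraries (0.568). With the tumour as a block the fry call was lost (adjusted p = 0.153). In a fit that left out the NP- library of tumour MET-106, 2 members rose, and without any other single library 0 did.

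Scavenger and Fc receptor genes fell for 4 of 23 members. They were Cd36, Colec12 (3.30 ± 1.13 against 15.1 ± 3.98 CPM), the LDL receptor family gene Lrp1 (2.76 ± 1.08 against 33.5 ± 40.4 CPM) and the Fc receptor gene Fcgr2b (0.984 ± 0.235 against 5.52 ± 2.89 CPM). Lrp1 stood at 79.8, 15.2 and 5.58 CPM in the NP- libraries of tumours MET-106, MET-107 and MET-108, with a mean of 10.4 CPM over the last 2, and the first of these had the highest fibroblast sum, 4681 CPM. The counts in olfactory receptor genes give 0.416 and 0.335 CPM per kb in the last 2, and Lrp1 has 17717 exonic bases. Whether Lrp1 exceeded this background in these 2 libraries stays open. The camera adjusted p was 0.00986, and the adjusted p was 0.240 with an estimated correlation. The fry adjusted p was 0.0328, and 0.153 with the tumour as a block. With upper-quartile and total-count scaling 9 and 10 members fell, and without the NP- library of tumour MET-106, 8. Without the NP+ library of tumour MET-106, MET-107 or MET-108, 0 members fell by edgeR, against 9 lower at an unadjusted p under 0.05, 9 by DESeq2 and 2 by limma-voom with all libraries, and 1 rose without the NP- library of tumour MET-108. The camera call was lost without the NP+ library of tumour MET-107 (adjusted p = 0.0679) or MET-108 (0.0753).

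Glycocalyx genes fell for 4 of 26 members, among them Hpse, the heparanase gene, at 0.155 ± 0.0602 CPM in NP+ and 3.48 ± 0.948 CPM in NP-, and the syndecan gene Sdc2 at 1.36 ± 0.438 against 18.5 ± 23.7 CPM. The NP- levels of Sdc2 in tumours MET-106, MET-107 and MET-108 were 45.8, 3.66 and 5.99 CPM, with a mean of 4.82 CPM over the last 2, and the fibroblast list summed to 4681, 284 and 105.7 CPM in the same libraries. Camera did not call the list (adjusted p = 0.916). With the tumour as a block 1 rose and 3 fell. In fits without the NP- library of tumour MET-106, MET-107 or MET-108, 1, 7 and 10 fell and 0, 1 and 3 rose, and without the NP+ library of tumour MET-106, MET-107 or MET-108, 1, 0 and 0 fell. At an unadjusted p under 0.05 3 rose and 8 fell with all libraries, 4 and 6 by DESeq2 and 0 and 1 by limma-voom. The level in NP- of 1 of the 4, Gpc6, lay within 2 times what the counts in olfactory receptor genes give.

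In the proliferation list 0 of 30 members passed by edgeR, with 2 higher at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom and 22 by DESeq2 with the tumour as a block. Mcm2, a replication licensing gene, stood at 105 ± 22.2 CPM in NP+ and 57.3 ± 19.1 CPM in NP- (adjusted p = 0.320, adjusted over the list alone). Camera called the proliferation list up (median log2 fold change 0.64, adjusted p = 2.31e-06, adjusted p = 0.519 with an estimated correlation). In the absence of the NP- library of tumour MET-106, 25 of its members rose.

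The antigen presentation list was called up by camera (adjusted p = 0.00588, adjusted p = 0.542 with an estimated correlation), as was the interferon list (adjusted p = 0.0391, adjusted p = 0.549 with an estimated correlation). In the antigen presentation list 0 of 16 members passed by edgeR, with 2 higher at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and 3 rose without the NP- library of tumour MET-108. In the interferon list 0 of 22 passed, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The antigen presentation call was lost without the NP+ library of tumour MET-107 (adjusted p = 0.0853) and among genes with at least 5 CPM in 3 libraries (0.679). The interferon call was lost with limma-voom (0.0528), with upper-quartile (0.155) and total-count scaling (0.187), and without the NP+ (0.0679) or NP- (0.125) library of tumour MET-107. Its median log2 fold change, 0.21, turned to -0.03 and -0.07 with these scalings.

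Camera did not call the lists of oxidative and metal stress (adjusted p = 0.121), immediate-early and dissociation response (0.941) or mitochondrially encoded genes (0.388). Klf4, an immediate-early transcription factor gene, was the 1 of 28 members of its list that fell, with 28.9 ± 2.12 CPM in NP+ and 56.2 ± 6.03 CPM in NP- (adjusted p = 0.0212, adjusted over the list alone). In that list 0 fell with the tumour as a block or without any single NP+ library, 3 fell without the NP- library of tumour MET-107, and 4 rose without that of tumour MET-106, with 5 lower at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom with all libraries. The list was called up without the NP- library of tumour MET-106 (adjusted p = 0.0151). With total-count scaling 5 fell. Among genes with at least 5 CPM in 3 libraries 5 fell and the list was called down (adjusted p = 0.00396, and 0.00344 with the block). In the oxidative list 0 of 21 members passed by edgeR, with 3 higher and 2 lower at an unadjusted p under 0.05, 2 and 1 by DESeq2 and 2 and 0 by limma-voom. In the blocked fit 1 rose, without the NP- library of tumour MET-108, 2 rose and 1 fell, and without the NP- library of tumour MET-106, 5 rose and 1 fell, with the list called up (adjusted p = 0.00837). It was also called up without the NP+ library of tumour MET-106 (0.0133) or MET-107 (0.0390), and its median log2 fold change of 0.18 turned to -0.07 and -0.11 with upper-quartile and total-count scaling. In the mitochondrial list 0 of 13 passed by edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and the list was called without the NP- library of tumour MET-108 (0.00741) and called down among genes with at least 5 CPM in 3 libraries (0.0440, and 0.0291 with the block).

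Most fibroblast, mural and epithelial markers were lower in NP+ cells. Those that fell were 16 of 17 fibroblast, 11 of 15 pericyte and smooth muscle and 14 of 16 epithelial genes. Col1a1, a fibrillar collagen gene, stood at 2.77 ± 1.65 CPM in NP+ and 224 ± 357 CPM in NP-, and the fibroblast receptor gene Pdgfra at 1.22 ± 0.712 against 14.0 ± 9.48 CPM. Myh11, a smooth muscle myosin gene, stood at 1.81 ± 1.81 against 36.5 ± 19.5 CPM and Notch3, a mural cell receptor gene, at 3.38 ± 2.17 against 18.2 ± 6.33 CPM. The epithelial adhesion genes Cdh1 and Epcam stood at 0.635 ± 0.429 against 16.8 ± 9.11 CPM and 0.434 ± 0.276 against 8.69 ± 10.5 CPM. Col1a1 stood at 637 CPM in the NP- library of tumour MET-106, and without that library the NP- means were 17.9 CPM for Col1a1, 8.55 for Pdgfra and 2.66 for Epcam. The NP+ means were 0.763 CPM for Myh11 and 2.24 for Notch3 without the NP+ library of tumour MET-106, 0.388 for Cdh1 without that of tumour MET-108 and 0.278 for Epcam without that of tumour MET-107. Of the genes that fell, Cspg4 (mural) and Dsp (epithelial), named after their values were seen, lay in NP- within 2 times what the counts in olfactory receptor genes give. The camera adjusted p was 1.38e-07 for fibroblast, 7.49e-07 for pericyte and smooth muscle and 3.16e-05 for epithelial genes, and the adjusted p was 0.339 for each with an estimated correlation. With the tumour as a block 13 fibroblast, 11 pericyte and 8 epithelial genes fell. By DESeq2 10, 12 and 10 were lower, and by limma-voom 3, 7 and 2. The 1 epithelial gene that rose was Spint2, a protease inhibitor gene named here after its values were seen, with 183 ± 14.1 CPM in NP+ and 108.2 ± 49.8 CPM in NP-. It did not pass without any single library other than the NP- library of tumour MET-106, nor with upper-quartile or total-count scaling.

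Much of this signal lay in the NP- library of tumour MET-106. The fibroblast list summed to 4681, 284 and 105.7 CPM in the NP- libraries of tumours MET-106, MET-107 and MET-108 and to 89.3, 74.6 and 37.0 CPM in the NP+ libraries. The pericyte and smooth muscle list summed to 1132, 338 and 202 CPM in NP- and to 147, 137 and 112 CPM in NP+. The epithelial list summed to 940, 205 and 119 CPM in NP- and to 221, 206 and 202 CPM in NP+. In a fit that left out the NP- library of tumour MET-106, 5 fibroblast, 5 pericyte and smooth muscle and 3 epithelial genes fell, and the epithelial camera call was lost (adjusted p = 0.193). Without the NP+ library of tumour MET-106 or MET-107, 9 epithelial genes fell. Leaving out both libraries of tumour MET-107, 5 epithelial genes fell, and 0 pericyte and smooth muscle genes did by edgeR, against 11 at an unadjusted p under 0.05 with all libraries.

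**Figure D4:**
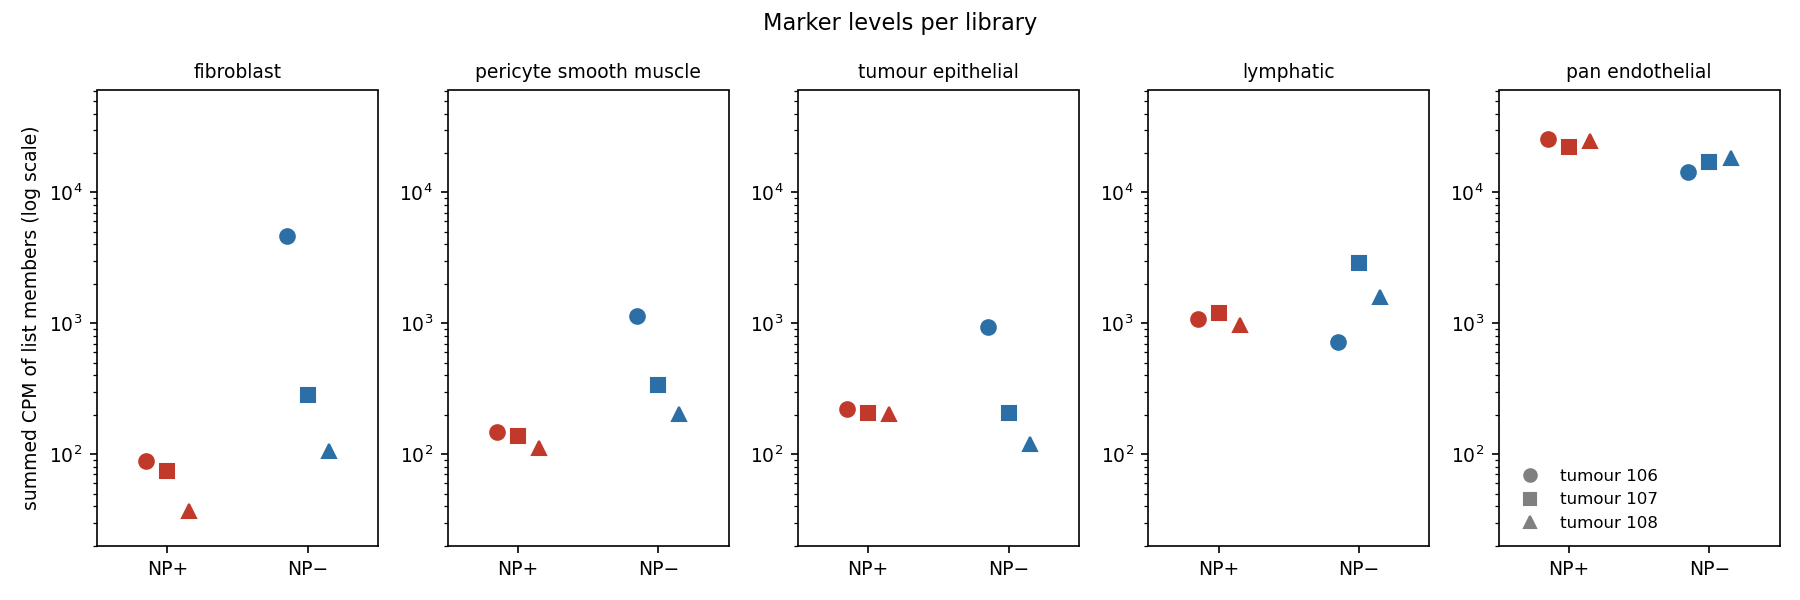
Summed CPM of all members of 5 marker lists (vertical axis, log scale) in each NP+ (red) and NP- (blue) library, with 1 symbol shape per tumour. The NP- library of tumour MET-106 has the highest fibroblast level, 4681 CPM, and the lowest pan-endothelial level, 14216 CPM.

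Neutrophil genes fell for 7 of 16 members and lymphocyte genes for 3 of 16. Il1b, the interleukin-1 beta gene, stood at 0.680 ± 0.447 CPM in NP+ and 6.07 ± 3.42 CPM in NP-, Retnlg at 0.207 ± 0.175 against 3.51 ± 1.90 CPM, and the T cell receptor complex gene Cd3g at 1.27 ± 0.194 against 5.13 ± 1.97 CPM. The NP+ mean was 0.428 CPM for Il1b without the library of tumour MET-107 and 0.123 for Retnlg without that of tumour MET-108. The camera adjusted p was 0.00114 for neutrophil and 0.0166 for lymphocyte genes, and the adjusted p was 0.339 and 0.323 with an estimated correlation. Both calls were lost without the NP- library of tumour MET-106 (adjusted p = 0.0741 and 0.253). The number of neutrophil genes that fell was 3 by limma-voom, 2 without the NP- library of tumour MET-107, 12 without that of tumour MET-108, and 4 and 3 without the NP+ libraries of tumours MET-106 and MET-107. The lymphocyte count was 0 with the tumour as a block, without the NP- library of tumour MET-107 and without any single NP+ library by edgeR, against 4 at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma-voom with all libraries. The counts in olfactory receptor genes, silent in most tissues, were also 5.48 times as high in NP- as in NP+ libraries, and the NP- level of 1 of the 7 neutrophil genes, Trem1, lay within 2 times what they give.

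Macrophage and monocyte genes were not called by camera (adjusted p = 0.153), and 0 of 24 members passed by edgeR, with 1 higher and 8 lower at an unadjusted p under 0.05, 1 and 8 by DESeq2 and 0 and 1 by limma-voom. Csf1r, a macrophage growth factor receptor gene, stood at 2.07 ± 1.19 against 8.33 ± 1.28 CPM and Cd14 at 185 ± 64.9 against 66.3 ± 43.7 CPM (adjusted p = 0.0593 for each, adjusted over the list alone). The NP+ mean of Cd14 was 2.79 times the NP- mean, and 4.50 times without the NP- library of tumour MET-106, which stood at 117 CPM. In the blocked fit 1 macrophage gene rose and 2 fell, with upper-quartile or total-count scaling 5 fell, and without the NP- library of tumour MET-108, 7 did and the list was called down (adjusted p = 0.0302). In fits without the NP- library of tumour MET-106, 1 rose and 1 fell. Among genes with at least 5 CPM in 3 libraries, 1 of 8 members rose and 3 fell, and the list was called down (adjusted p = 0.0342, but 0.0502 with the block). With the block, the list-alone adjusted p was 0.0325 for Csf1r and 0.00562 for Cd14. In the platelet list Itgb3, an integrin gene that endothelium also expresses, was the 1 of 11 members that rose, with 555 ± 48.7 CPM in NP+ and 207 ± 73.7 CPM in NP- (0.00749). The platelet and adipocyte lists had median log2 fold changes of -1.15 and -0.85 while their camera tests pointed up (adjusted p = 0.868 for each). In the adipocyte and erythroid lists 0 of 7 members each passed by edgeR, with 0 and 1 lower at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The erythroid list was not called by camera (0.388) but was called down without the NP- library of tumour MET-107 (0.00102), with 3 members lower.

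At an adjusted p under 0.05, the authors' deposited table held 938 genes higher in NP+ and 2390 higher in NP-. All 7 genes called here were among them, and 2928 of the authors' calls were tested here, all with the same sign. Both comparisons rest on the same counts, so the shared sign is no independent support. With the tumour as a block 15 calls were shared. The DESeq2 fit to the same counts called 976 genes higher and 3147 lower in NP+, of which 898 and 2381 were also in the authors' deposited table. Counts were simulated for 23989 genes with the estimated dispersions, equal in both groups, and with 100 genes changed 2-fold and 100 changed 4-fold. In them DESeq2 called 194 genes, 81 of them unchanged (41.8%), and recovered 26% of the 2-fold and 87% of the 4-fold changes. The edgeR test called 79, 7.59% of them unchanged, and recovered 3% of the 2-fold and 70% of the 4-fold changes. With the dispersion lowered to 0.05, 8.14% of the DESeq2 and 1.34% of the edgeR calls were unchanged. The estimated dispersions were edgeR's own, the changed genes had a mean of at least 5 CPM, and the runs were not repeated. These shares depend on how few genes were changed, so they do not carry over to the calls on the real counts.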

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

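The test of other silent gene families was chosen only after the result was seen. Olfactory receptor genes left out by the low-count filter (655 genes) carried counts in every library, above the limit that a count of 0 allows. They held 23.2, 89.9 and 44.4 CPM in the NP+ libraries of tumours MET-106, MET-107 and MET-108, and 82.6, 546 and 302 CPM in the NP- libraries. The limits (3 counts) were 0.0717, 0.0516, 0.0668, 0.0671, 0.144 and 0.110 CPM in the same order, for counting error only.

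Over all 1134 olfactory receptor genes the level was 192 ± 112 CPM in NP+ and 1053 ± 676 CPM in NP-. Transcription of these receptors in NP- cells, the 1 biological explanation tested, is argued against, since vomeronasal receptor, keratin-associated and beta-defensin genes were also higher, by 5.00 to 6.13 times. With any 1 library left out the folds ran from 3.17 (beta-defensin, without the NP- library of tumour MET-107) to 10.2 (vomeronasal, without the NP+ library of tumour MET-107). Genomic DNA carried into the libraries may account for the olfactory receptor counts. The 10 highest of these genes held at most 8.53% of them in the NP- libraries of tumours MET-107 and MET-108. For 295 vomeronasal genes the share was at most 23.4%. It was 64.2% and 83.8% for 56 keratin-associated genes, and 77.6% and 91.3% for 42 beta-defensin genes. In the NP- library of tumour MET-108, 750 of the 1134 olfactory receptor genes had a count. How even a spread genomic DNA would give was not tested. How far this background feeds the 3147 DESeq2 calls higher in NP- stays open: 17.8% differed by at most 2 times the background expected from gene length, and 88.0% had a mean under 5 CPM.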

How the results depend on the processing

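Robust shrinkage, the tumour block with a 5 CPM filter, limma-voom with the block and recovered reads were chosen only after the result was seen. The 7 called genes kept their sign in every setting. Genes higher and lower in NP+ (3 and 4) were 2 and 13 with the replicate block, 976 and 3147 with DESeq2, 1352 and 2944 with DESeq2 and the block, and 12 and 6 with limma-voom. They were 486 and 1077 with limma-voom and the block, 3 and 18 with upper-quartile and 2 and 9 with total-count scaling. They were 525 and 686 without a low-count filter, 18 and 87 with at least 5 CPM in 3 libraries, 44 and 183 with that filter and the block, and 121 and 124 at an adjusted p under 0.1. With robust shrinkage they were 4 and 5. With 1 library or tumour left out they ran from 0 to 968 and from 0 to 1352, with fewer samples. The cause of the other shifts was not tested. The agreement with the authors' deposited comparison, as calls shared with the authors' deposited table, was 7 genes, 15 with the replicate block and 3279 with DESeq2.

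The 21 lists called were 0 with an estimated correlation, 0 with it and the block, and 6 with fry. With the 5 CPM filter, the replicate block took macropinocytosis from an adjusted p of 0.0440 to 0.0765 and macrophage genes from 0.0342 to 0.0502. With edgeR and filterByExpr it changed no list call. Counts of members changed too, as for fibroblast (16 to 13), neutrophil (7 to 5) and scavenger genes (4 to 6), and moved by over 1.5 times only where given beside the result. Camera directions turned, with these adjusted p, for lists not called in the main test unless named otherwise. For glycocalyx it was 0.919 with the block, 0.936 with limma-voom, 0.643 with no filter, 0.958 with recovered reads and 0.958 with an estimated correlation and the block. For immediate-early genes it was 0.884 with the block, 0.957 with RLE, 0.185 with no filter, 0.984 with limma-voom and the block, 0.878 with recovered reads and 0.946 with an estimated correlation and the block. Platelet genes turned with limma-voom (0.936) and fry (0.518), adipocyte genes with fry (0.727) and capillary genes with no filter (0.643). With the 5 CPM filter, without and with the block, the called interferon list turned (0.774 and 0.737), as did junctions (0.862 and 0.673) and oxidative stress (0.499 and 0.531). The ranges that follow cover every fit with a library or tumour left out, whether or not the direction turned. They were 0.109 to 0.974 for capillary, 0.0956 to 0.993 for glycocalyx, 0.0151 to 0.997 for immediate-early, 0.00741 to 0.875 for mitochondrial and 0.390 to 0.992 for platelet genes. The cause was not tested. Without tumour MET-106 the lymphocyte (0.217), neutrophil (0.148), scavenger (0.0660) and epithelial (0.233) calls were lost. Without tumour MET-107 the antigen (0.520), inflammatory (0.106), interferon (0.521), lymphatic (0.107) and scavenger (0.0592) calls were lost. In counts simulated at these totals edgeR recovered 3% of 2-fold and 70% of 4-fold changes, and 47% and 100% with the dispersion lowered to 0.05. DESeq2 recovered 26% and 87%, and 58% and 100% with the lowered dispersion.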

Other observations

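The 5 gene lists described first, and all tests weighed after them except those of Adipoq and of list members under other splits, were chosen only after the result was seen. Genes of tumour endothelial markers were higher for 4 of 16 members and lower for 3 when adjusted over the list alone. Besides Cd276, Esm1 and Apln, Hlx, a homeobox gene, stood at 55.1 ± 5.84 CPM in NP+ and 14.9 ± 4.52 CPM in NP-. Camera called the list up (adjusted p = 0.00172, adjusted p = 0.252 with an estimated correlation), with a median log2 fold change of 0.13 and a mean of -0.23. Camera p values of these 5 lists are adjusted over the 5 alone. Because Cd276, Esm1 and Apln had already been seen to be higher, the call is no independent support. The median turned to -0.13 and -0.17 with upper-quartile and total-count scaling. Targets of TGF-beta, BMP and YAP signalling were higher for 5 of 23 members and lower for 2 (2 and 2 with the tumour as a block, camera adjusted p = 0.136). Bmp2, a BMP ligand gene, stood at 102 ± 11 against 26.3 ± 10.6 CPM and the matricellular gene Ccn2 at 1123 ± 310 against 273 ± 102 CPM, while Tgfb3 stood at 4.07 ± 1.06 against 22.9 ± 7.11 CPM. The higher and lower counts were 3 and 2 without the NP- library of tumour MET-107 or the NP+ library of tumour MET-106, 7 and 5 without the NP- library of tumour MET-108, and 2 and 2 without the NP+ library of tumour MET-108.

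Semaphorin and plexin genes were higher for 6 of 31 members and lower for 6 (camera adjusted p = 0.538), among them the semaphorin genes Sema6d (317 ± 31.0 against 119 ± 49.8 CPM) and Sema6b (37.5 ± 1.99 against 13.6 ± 0.354 CPM), which were higher, and Sema3e (1.05 ± 0.258 against 6.69 ± 2.27 CPM), which was lower. Of the 6 lower members 3, Sema5a, Plxna3 and Sema3c, lay in NP- within 2 times what the counts in olfactory receptor genes give. With upper-quartile or total-count scaling 3 were higher. The counts were 5 and 9 and 6 and 3 without the NP- library of tumour MET-106 or MET-107, 5 and 3 and 4 and 1 without the NP+ library of tumour MET-106 or MET-108. Of 19 Eph receptor and ephrin genes 1 was higher, Ephb4 (2 with the tumour as a block), and 4 were lower, among them Efna5 (1.07 ± 0.625 against 7.04 ± 2.69 CPM, with an NP+ mean of 0.712 without the library of tumour MET-107). Of these 4, Ephb2 lay within 2 times that background. Without the NP+ library of tumour MET-106 or MET-108, 0 were lower by edgeR, against 6 at an unadjusted p under 0.05, 7 by DESeq2 and 4 by limma-voom with all libraries. Fatty acid handling genes were higher for 1 of 17 members, the transporter gene Slc27a4 (21.6 ± 3.11 against 6.31 ± 2.44 CPM), and lower for 3, Lpl, Aqp7 and Cd36 (camera adjusted p = 0.538).

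Most fibroblast, mural and epithelial markers had a higher mean in NP- than in NP+ libraries. The summed epithelial level was higher in NP- in tumour MET-106 (940 against 221 CPM). It was not in MET-107 (205 against 206 CPM) or MET-108 (119 against 202 CPM). In tumour MET-106 background like that in olfactory receptor genes is argued against, as the median member stood at 129 times the level it gives. In tumours MET-107 and MET-108 the median was 4.13 times, and this background stays open. Other cell types in the NP- library of tumour MET-106 stay open too: 97.9% of the 48 tested members (47) were higher there than in the NP+ library, among them Col1a1 at 637 CPM, but this restates the pattern and decides nothing. The enrichment for CD31 was meant to lower the share of such cells, but its purity is not given in the sources used here. Of the fibroblast genes 1 is in another list, and 3 fibroblast, 7 pericyte and 2 epithelial genes stood at 5 CPM or more in NP+.

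Of the members passing over the list alone, 11 tip cell genes were higher in NP+, while 7 arterial and 7 capillary genes were lower and 2 and 3 higher, with neither of these lists called by camera. A lower endothelial share in NP- libraries would move all endothelial genes alike. For tip cell genes it stays open: they exceeded pan-endothelial genes in 3 of 3 tumours (by 0.79, 0.33 and 0.04 on the log2 scale), but the mean excess, 0.38 ± 0.376 (SD), lay within 2 SD of 0. The 36 arterial and capillary genes lay below pan-endothelial genes in 3 of 3 tumours, with a mean difference of -0.68 ± 0.171. This argues against a lower share alone only if other cell types add no counts of these genes, which was not tested. Adipocytes as the source of Lpl and Aqp7 are argued against by Adipoq, at most 0.624 CPM in NP- libraries, and nanoparticle uptake by endothelial subtype stays open, as untested.

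The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3 genes higher, 4 lower, 21 lists and 146 list members, in 1 of the 10 splits each. The highest of the other splits gave 0, 0, 16 and 22. Each NP+ library shares its tumour with 1 NP- library, and 4 of the 10 splits part all 3 such pairs. Besides the real one, these gave 0 genes, 14 to 16 lists and 0 to 15 members, and the 6 that part 1 pair gave 0 genes, 12 to 16 lists and 0 to 22 members.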
